A study of Homo sapiens with 10 samples.

How the data were processed

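Total RNA of MCF7 cells was measured on single-colour Illumina BeadChip arrays with Cy3 in 10 samples, 2 for each of 5 groups. The deposited values are probe intensity per sample, which per the labels are BeadStudio means of 2 arrays with no normalization. The smallest deposited value was 35 and the largest 63539.5, with none at or below 0. Per the labels each group had 4 technical repeats, and 20 scanner tables were deposited beside the value table.

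The deposited value table of 48803 probes was the source of all named values. Intensities were background corrected with normexp at an offset of 50, quantile normalized and taken to log2. A probe was tested where its deposited signal exceeded the array median in both samples of at least 1 group, which left 26344 probes and set aside 22459. All 5 groups entered a single limma fit with moderated variances, and 9 comparisons were drawn from it: each drug at each day against untreated, the drugs against each other at each day, day 7 against day 1 for each drug, and the interaction. Residual degrees of freedom were 5, prior degrees of freedom 9.27 and the prior SD 0.102. The median SD within groups was 0.0986 on the log2 scale. P-values were adjusted by Benjamini-Hochberg within each comparison, a probe was called at an adjusted p below 0.05, and the count changed at least 2-fold was given beside it. All tests were two-sided. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used.

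Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 33 lists and 9 comparisons together, and again with a correlation estimated from the data and with fry. A gene was represented in a list by its probe with the highest mean. Probe symbols came from the older platform annotation and were updated through gene numbers for 27541 probes, while 50 kept the old symbol. Of all probes 27578 had 1 symbol, 13 had several and 21212 had none, and the annotation held no coordinates, so no positions are given. Among tested probes 17975 had a single symbol, covering 13494 genes. A group was called at background where both samples lay at or below the array median, and such folds are given as lower bounds. No size is given for an interaction with more than 1 group at background, or for DNMT3A where only the mean of a group lay there.

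Named genes followed a rule fixed, like the comparisons, lists and most alternatives, before the data were examined. It took the 8 largest rises and 8 largest falls of each comparison with untreated cells and 5 and 5 of each other comparison, among calls in which both samples of a group lay on the same side of both samples of the other, with 1 symbol and 1 probe per gene and without placeholder names. It added up to 4 members of each list that passed or had at least 3 calls, and 15 genes reported throughout. Overlaps between drugs were set against simulations of unchanged groups that shared their controls.

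The alternatives were cyclic loess, scaling to a common median, no normalization, a normexp offset of 16, no background correction, no filter, a filter in all samples (16253 probes), fits of only the groups compared, eBayes with trend and robust, the replicate letter as a block, stricter thresholds, averaging the probes of a gene, all tested probes of the genes in the lists, each sample left out in turn, and the 20 scanner tables in place of the value table. The scanner tables carry bead type codes that could not be matched to probe names, so they gave counts only. Fits without 2 of the scanner tables and fits with 1 untreated sample as the control of each drug were added after the data were seen.

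The pipeline was tested on simulated data in which 200 of 26344 probes were changed. For DZNep day 7 against untreated, 73% of 1.41-fold, 91% of 2-fold and 88.5% of 4-fold changes were recovered. For 5-Aza-CdR day 7 these were 53.5%, 87% and 88.5%, with 58% of the 1.41-fold rises and 49% of the 1.41-fold falls. Rises of 2-fold and 4-fold were recovered in 100% of cases, so the missed changes of that size were falls of dim probes. Between 8 and 16 unchanged probes were called per run. As many probes rose as fell in these runs, and in 1 group only. They do not test the normalization where many probes change, such as the 37.4% called at day 1 of DZNep.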

Results

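Gene expression was measured in MCF7 cells, an established estrogen receptor-positive breast cancer line, after treatment with DZNep or with 5-Aza-CdR. DZNep (3-deazaneplanocin A) inhibits S-adenosylhomocysteine hydrolase, the enzyme encoded by AHCY, and is used to lower the activity of methyltransferases such as the Polycomb enzyme EZH2. 5-Aza-CdR (decitabine) is incorporated into DNA and traps DNA methyltransferases. Cells of either drug were harvested at day 1 or day 7, and untreated cells were the control. The sample titles give only the day and do not say how long the drug was present. There were 5 groups of 2 samples, A and B, and each sample was the mean of 2 arrays. The labels give no dose, and they give no harvest day for the untreated cells, which therefore served as the control for both days. The design statement calls the 4 arrays of a group technical repeats, so every p-value below measures the spread between repeats and not between independent cultures.

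The value table held 48803 probes, and 26344 of them passed the signal filter and were tested. Mean raw intensity was 466.9 and 587.1 in the untreated samples, 319.5 and 335.7 in 5-Aza-CdR day 1, 314 and 366.5 in 5-Aza-CdR day 7, 273.9 and 261.1 in DZNep day 1, and 298.3 and 410.2 in DZNep day 7. Both untreated samples were thus brighter than all 8 treated samples. After normalization the samples of a group correlated at 0.993 to 0.997 across the tested probes, with median absolute differences of 0.09 to 0.12 on the log2 scale. Changes are given on the log2 scale with the standard error (SE) of the shared fit and 2 samples per group. Unless stated otherwise, a named gene lay on the same side of the other group in both of its samples. Ranks are among probes with a single gene symbol that is not a placeholder. For arrays, the number of samples limits the precision.

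The question of the first set of comparisons was which genes each drug changed relative to untreated cells at each harvest. With DZNep, 4576 probes rose and 5279 fell at day 1, of which 648 and 535 changed at least 2-fold. At day 7 of DZNep, 583 rose and 288 fell, 22 and 3 of them at least 2-fold. With 5-Aza-CdR, 3767 rose and 4277 fell at day 1 (355 and 261 at least 2-fold), and 2847 rose and 2845 fell at day 7 (327 and 104 at least 2-fold).

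**Figure D1:**
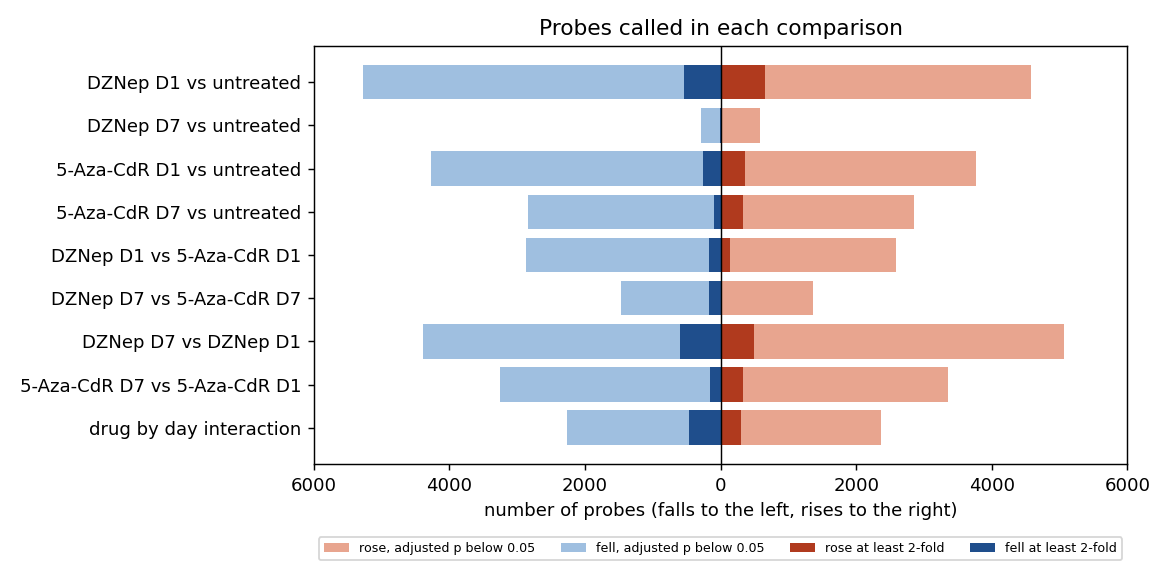
Number of probes that passed at an adjusted p of 0.05 in each of the 9 comparisons, on a linear axis. Bars to the right count rises and bars to the left count falls, with the part that changed at least 2-fold in the darker shade. DZNep day 7 against untreated has the shortest bars, 583 rises and 288 falls.

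The largest rise at day 1 of DZNep was that of KRT13, a keratin of stratified epithelium (3.37 ± 0.09, 10.4-fold). It was followed by ARHGDIB, a regulator of Rho GTPases (3.28 ± 0.11, 9.72-fold), and TGM2, tissue transglutaminase (3.1 ± 0.1, 8.57-fold). The smooth muscle actin ACTG2 rose by 2.78 ± 0.11, the adhesion scaffold NEDD9 by 2.77 ± 0.09, the keratin KRT16 by 2.74 ± 0.13, the endothelin precursor EDN1 by 2.7 ± 0.16 and the tropomyosin TPM2 by 2.6 ± 0.11. The largest fall was that of the adenylate cyclase ADCY1, which fell by 3.35 ± 0.12 (10.2-fold). The carbonic anhydrase CA2 fell by 1.98 ± 0.11, the myosin MYO5C by 1.98 ± 0.09, the lectin-like receptor CLEC2D by 1.93 ± 0.24, the neurotrophic factor co-receptor GFRA1 by 1.92 ± 0.1, the ribosomal protein RPL17 by 1.86 ± 0.11, IMPDH2, an enzyme of guanine nucleotide synthesis, by 1.86 ± 0.11, and NIPSNAP1 by 1.81 ± 0.09. Adjusted p-values of these 16 genes ranged from 1.09e-11 to 1.62e-05 (limma). Other probes of TGM2 changed by 0.65 and 0.62, those of NEDD9 by 0.66, 0.57 and 1.17, that of KRT16 by 0.76 and that of CLEC2D by 0.14.

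Genes of the estrogen response fell as a group at day 1 of DZNep, with 24 of 38 falling and 5 rising (25 and 7 adjusted over the list alone; camera adjusted p = 0.000162, and adjusted p = 0.183 with an estimated correlation). The receptor gene ESR1 fell by 1.57 ± 0.12, its target GREB1 by 1.53 ± 0.11 (other probes at -0.11, -0.04 and -0.07) and MYB by 1.38 ± 0.09. PGR, the progesterone receptor, fell by 0.84 ± 0.09 and TFF1 by 0.32 ± 0.1. Among cytoplasmic ribosomal proteins 37 of 67 fell and 10 rose (38 and 12 adjusted over the list alone; camera adjusted p = 1.89e-05, and adjusted p = 0.154 with an estimated correlation), with RPS12 falling by 1.35 ± 0.1 and RPL37 rising by 1.21 ± 0.09. In the respiratory chain list 24 of 55 fell and 5 rose (26 and 7 adjusted over the list alone), at a camera adjusted p of 0.00127 and an adjusted p = 0.316 with an estimated correlation. NDUFS4, a subunit of complex I, fell by 1.16 ± 0.15. Mitosis genes fell in 21 of 47 cases and rose in 7 (23 and 7 adjusted over the list alone; camera adjusted p = 0.0446, and adjusted p = 0.359 with an estimated correlation). The mitotic kinase CDK1 fell by 1.17 ± 0.11, whereas CENPF rose by 1.11 ± 0.09 but stood at -0.12 without normalization and at 0.03 (adjusted p = 0.932) with scaling to a common median. The rise of RPL37 was not called with that scaling (0.31, adjusted p = 0.147) or without normalization (0.16, 0.373). The mitosis list no longer passed without either untreated sample (adjusted p = 0.0543 without A and 0.0514 without B) or without DZNep day 1 A (0.0774), and with cyclic loess it stood at 0.0625.

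Inflammatory genes rose at day 1 of DZNep in 12 of 28 cases and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.0728 with an estimated correlation, with a median of 0.22 that became -0.11 without normalization). The calcium-binding protein S100A8 rose by 1.41 ± 0.11 and the NF-kB inhibitor NFKBIA by 1.14 ± 0.1, the latter at 0.13 (adjusted p = 0.666) with scaling to a common median and at -0.02 without normalization. Of the mesenchymal and basal markers 9 of 17 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.128 with an estimated correlation, with a median of 0.32 that became -0.3 with scaling to a common median, where the list stood at 0.263, and -0.45 without normalization), among them the transcription factor SNAI2 by 2.12 ± 0.1, TAGLN by 1.73 ± 0.12 and ITGA5 by 1.42 ± 0.11. Markers of blood cells, a cell type the line does not contain, moved with these groups. Of these, 6 of 15 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00706, and adjusted p = 0.301 with an estimated correlation, with a median of 0.19 that became -0.13 without normalization), including CD68 by 1.57 ± 0.14, which was not called with scaling to a common median (0.49, adjusted p = 0.277) or without normalization (0.35, 0.378) and had other probes at 0.46 and 0.18. The list of genes repressed by Polycomb or induced by DZNep in cancer cells rose in 11 of 26 cases and fell in 6 (11 and 6 adjusted over the list alone; camera adjusted p = 0.0453, and adjusted p = 0.359 with an estimated correlation, with a median of 0.19 that became -0.25 with scaling to a common median, where the list stood at 0.332, and -0.4 without normalization), including IGFBP3 by 1.48 ± 0.09 and DLC1 by 1.2 ± 0.1. That list did not pass without DZNep day 1 A, at an adjusted p of 0.115, or with the replicate letter as a block (0.0525). The same list also passed upward at day 1 of 5-Aza-CdR (camera adjusted p = 0.0182). There it did not hold with an estimated correlation or without 5-Aza-CdR day 1 A. Across genes with a pair of bright probes, 86 of the 395 pairs with both probes called at day 1 of DZNep moved in opposite directions (21.8%).

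Among the 15 genes reported for every comparison, DNMT3A, a de novo DNA methyltransferase, rose at day 1 of DZNep at least 1.81-fold from a signal at background. DNMT3B rose by 0.76 ± 0.13, with other probes between -0.02 and 0.48. FBXO32, a ubiquitin ligase component studied as an EZH2 target, rose by 0.49 ± 0.11, with other probes at 0.28 and 0.11, and the cell cycle inhibitor CDKN1A by 0.47 ± 0.15, with another probe at 0.04. EZH2 rose by 0.33 ± 0.1 with the brightest probe, while its other probes changed by -0.33 and -0.47. AHCY fell by 0.58 ± 0.11, EED, a partner of EZH2, by 0.48 ± 0.09, the DNMT1 partner UHRF1 by 0.75 ± 0.11 and the proliferation marker MKI67 by 0.26 ± 0.1. SUZ12, DNMT1 and GSTP1 did not pass, with changes from -0.2 to 0.03. Without normalization EZH2 stood at -0.85, DNMT3B at -0.43, FBXO32 at -0.29 and CDKN1A at -0.78, and with scaling to a common median at -0.71, -0.29, -0.14 and -0.63. Of these calls EZH2, TFF1, CDKN1A and MKI67 depended on single samples. Without Untreated A the changes were 0.35 for EZH2, -0.26 for TFF1, 0.46 for CDKN1A and -0.26 for MKI67, at adjusted p-values of 0.0522, 0.15, 0.0984 and 0.133. Without Untreated B the adjusted p-values of EZH2, CDKN1A and MKI67 were 0.0948, 0.0932 and 0.145. Without DZNep day 1 A those of TFF1, CDKN1A and MKI67 were 0.0591, 0.287 and 0.235, with CDKN1A down to 0.26, without DZNep day 1 B those of EZH2 and TFF1 were 0.12 and 0.095, and without either 5-Aza-CdR day 7 sample that of MKI67 was 0.0571. With cyclic loess TFF1 stood at -0.25 (0.0585) and MKI67 at -0.24 (0.0523). Without normalization or with scaling to a common median the split of the calls at day 1 of DZNep became 134 rises and 14972 falls, or 317 and 11180, instead of 4576 and 5279.

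At day 7 of DZNep the largest rise was that of ANXA1, the phospholipid-binding annexin A1 (2 ± 0.09, 4-fold, adjusted p = 6.31e-08, limma). Of the interferon response IFI27 rose by 1.45 ± 0.12 (2.73-fold), IFI6 by 1.33 ± 0.16 (2.51-fold) with another probe at 0.46, and IRF9, a transcription factor of the interferon pathway, by 1.14 ± 0.09 (2.21-fold). The dehydrogenase DHRS2 rose by 1.36 ± 0.11, the chloride channel protein CLIC3 by 1.34 ± 0.2, the netrin NTN4 by 1.2 ± 0.12 and the transcription factor KLF2 by 1.16 ± 0.11. Most of these calls ended with scaling to a common median, where IFI27 stood at 1.1 (adjusted p = 0.0575), IFI6 at 0.74 (0.182), IRF9 at 0.6 (0.0861), DHRS2 at 0.93 (0.0742), CLIC3 at 0.75 (0.0564) and KLF2 at 0.69 (0.118). Without normalization IFI6 (0.66, adjusted p = 0.154), IRF9 (0.52, 0.0692) and KLF2 (0.62, 0.0989) were not called either. The largest fall was that of the imprinted noncoding RNA H19, which fell by 1.41 ± 0.1 (2.66-fold). The nuclear receptor NR5A2 fell by 1.17 ± 0.09, with other probes at -0.16 and -0.67, the histone gene H4C3 by 1.01 ± 0.22, RPL36A by 0.87 ± 0.1, TUBB2B by 0.86 ± 0.1, the glutathione peroxidase GPX2 by 0.85 ± 0.12, the co-chaperone FKBP4 by 0.83 ± 0.12 and the transporter SLC35C1 by 0.81 ± 0.17. Without DZNep day 7 A the fall of H4C3 was only 0.46 (adjusted p = 0.0381) and the rise of CLIC3 0.86 (0.00176). H4C3 did not pass without either untreated sample (adjusted p = 0.142 without A and 0.119 without B), and SLC35C1 did not pass without Untreated B (0.194) or DZNep day 7 A (0.12). H4C3 was at -1.55 (0.0666) and SLC35C1 at -1.3 (0.0611) with scaling to a common median.

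Of the interferon genes 12 of 46 rose and none fell at day 7 of DZNep (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.58e-09, and adjusted p = 0.0568 with an estimated correlation, with a median of 0.09 that became -0.03 with scaling to a common median and -0.11 without normalization). OAS3, an antiviral enzyme, rose by 0.95 ± 0.1 with another probe at 0.17. With scaling to a common median it rose by 0.54 (adjusted p = 0.0561), and 0 of the 46 genes passed by limma. Without normalization 3 of the 46 rose and 3 fell. Immediate early and AP-1 genes rose in 12 of 27 cases with no fall (15 and 0 adjusted over the list alone; camera adjusted p = 5.81e-10, and adjusted p = 0.0771 with an estimated correlation, with a median of 0.29 that became -0.09 with scaling to a common median and -0.16 without normalization), including FOSB by 1.1 ± 0.1, IER5 by 1.06 ± 0.12 and ATF3 by 0.9 ± 0.11. The list did not pass with scaling to a common median (adjusted p = 0.133), where FOSB stood at 0.5 (0.183), IER5 at 0.47 (0.0624) and ATF3 at 0.47 (0.115). Without normalization FOSB (0.42, adjusted p = 0.18) and ATF3 (0.39, 0.0989) were not called. Mesenchymal and basal markers rose in 7 of 17 cases and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 9.68e-08, and adjusted p = 0.0275 with an estimated correlation, with a median of 0.26 that became -0.06 with scaling to a common median and -0.14 without normalization), with SNAI2 rising by 1.09 ± 0.1 and TGFBI falling by 0.75 ± 0.1. The DNA replication list fell as a whole, with 3 of 49 members falling and none rising (5 and 0 adjusted over the list alone; camera adjusted p = 1.01e-06, and adjusted p = 0.0379 with an estimated correlation). Its median change was -0.18. Ribosomal proteins fell in 8 of 67 cases (19 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.52e-08, and adjusted p = 0.101 with an estimated correlation). Cancer-testis genes, which are normally expressed in germ cells, did not move as a group, with 1 of 54 rising, none falling and a camera adjusted p of 0.626. Fibroblast markers rose in 2 of 10 cases (2 adjusted over the list alone; camera adjusted p = 0.0032, and adjusted p = 0.13 with an estimated correlation, with a median of 0.18 that became -0.07 without normalization), which was not the case without DZNep day 7 B (adjusted p = 0.0502).

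Of the 15 genes reported throughout, FBXO32 passed at day 7 of DZNep, with a rise of 0.73 ± 0.11 and other probes at 0.14 and 0.21. AHCY, EZH2, EED, SUZ12, DNMT1, DNMT3A, DNMT3B, UHRF1, ESR1, PGR, TFF1, GSTP1, CDKN1A and MKI67 did not pass, with changes between -0.38 and 0.06 and adjusted p-values of 0.108 or more. The count at day 7 of DZNep moved with single samples. It was 871 with all samples, 273 without Untreated A, 258 without Untreated B and 1524 without DZNep day 7 B. Cyclic loess gave 870 rises and 663 falls, scaling to a common median 11 and 958, and no normalization 32 and 6631, beside 583 and 288.

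At day 1 of 5-Aza-CdR the largest rise was that of the small noncoding RNA SNAR-A1 (3.06 ± 0.47, 8.33-fold). It was followed by HAUS2, a subunit of the augmin complex (2.08 ± 0.16, 4.24-fold), the cytokine TNFSF14 (2.02 ± 0.17, 4.05-fold) and the zinc finger gene ZNF223 (1.91 ± 0.15, 3.75-fold). DCLRE1C, the Artemis nuclease, rose by 1.87 ± 0.13, with other probes at 0 and 0.76, the bicarbonate transporter SLC4A5 by 1.79 ± 0.13, MBTD1 by 1.78 ± 0.12 and EVI5 by 1.77 ± 0.15. HAUS2, TNFSF14, ZNF223 and SLC4A5 stood at similar intensities, from 9.6 to 10.2 in untreated samples and from 11.61 to 12.04 at day 1 of 5-Aza-CdR. Whether their probes read separate transcripts was not tested. The largest falls were those of TMEM64, which fell by 1.91 ± 0.12, the cytoskeletal genes ACTG1, which fell by 1.74 ± 0.16, and TUBA1A, which fell by 1.71 ± 0.15, and the zinc transporter SLC39A6, which fell by 1.71 ± 0.12. GFRA1 fell by 1.56 ± 0.1, the glycolytic enzyme ALDOA by 1.52 ± 0.15, the elongation factor EEF1A1 by 1.52 ± 0.13 and DTYMK, an enzyme of thymidine nucleotide synthesis, by 1.5 ± 0.09. Adjusted p-values of the 16 genes ranged from 2.82e-07 to 0.000163 (limma). Other probes changed by -0.32 for ACTG1, -0.24 for TUBA1A, 0.06 and -0.39 for ALDOA, -0.22 and -1.45 for EEF1A1, and 0.3 for DTYMK.

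Ribosomal proteins fell as a group at day 1 of 5-Aza-CdR, with 40 of 67 falling and 8 rising (42 and 12 adjusted over the list alone; camera adjusted p = 2.83e-07, and adjusted p = 0.118 with an estimated correlation). RPL22 fell by 1.34 ± 0.12 and RPL41 by 1.28 ± 0.09. In the respiratory chain list 27 of 55 fell and 6 rose (28 and 7 adjusted over the list alone; camera adjusted p = 3.88e-05, and adjusted p = 0.216 with an estimated correlation), with NDUFS4 falling by 1.46 ± 0.15 and UQCRH by 1.06 ± 0.1. Housekeeping genes fell in 11 of 25 cases with no rise (11 and 0 adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.259 with an estimated correlation). That list did not pass with cyclic loess (adjusted p = 0.0633) or without 5-Aza-CdR day 1 B (0.0585). Estrogen response genes fell in 17 of 38 cases and rose in 6 (17 and 8 adjusted over the list alone; camera adjusted p = 0.0328, and adjusted p = 0.359 with an estimated correlation), which was lost without 5-Aza-CdR day 1 A (adjusted p = 0.0638). The protease CTSD fell by 1.32 ± 0.11 and the amino acid transporter SLC7A5 rose by 1.33 ± 0.11. Luminal markers fell in 13 of 27 cases and rose in 3 (15 and 4 adjusted over the list alone; camera adjusted p = 0.0163, and adjusted p = 0.128 with an estimated correlation), with the luminal transcription factor GATA3 falling by 0.81 ± 0.12; the list did not pass with cyclic loess (adjusted p = 0.0596).

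Inflammatory genes rose at day 1 of 5-Aza-CdR in 11 of 28 cases and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.112 with an estimated correlation, with a median of 0.14 that became -0.04 without normalization), among them the NF-kB regulator NFKBIZ by 1.15 ± 0.09 and the chemokine CXCL16 by 1.06 ± 0.11. Neither was called with scaling to a common median (NFKBIZ 0.38, adjusted p = 0.16, and CXCL16 0.29, 0.409) or without normalization (0.28, adjusted p = 0.226, and 0.19, 0.546). Blood cell markers moved with them, with 3 of 15 rising and 1 falling (3 and 1 adjusted over the list alone; camera adjusted p = 0.0378, and adjusted p = 0.363 with an estimated correlation, with a median of 0.13 that became -0.08 without normalization). CD68 rose by 1.67 ± 0.14 and CD14 by 1.2 ± 0.1, and the list did not pass without Untreated B (adjusted p = 0.0747) or without 5-Aza-CdR day 1 A (0.0606). Neither cancer-testis genes (3 of 54 rose, 1 fell, camera adjusted p = 0.526) nor interferon genes (10 of 46 rose, 3 fell, camera adjusted p = 0.176) moved as a group at day 1. IFI6 rose by 1.47 ± 0.16, but its other probe stood at -0.35. Other probes of CD68 stood at 0.39 and -0.01 and that of NFKBIZ at 0.05. IFI6 stood at 0.71 (adjusted p = 0.16) and CD68 at 0.92 (0.0683) with scaling to a common median, and without normalization at 0.61 (0.168) and 0.82 (0.065). Of the 342 gene pairs of probes with both called at this harvest, 86 moved in opposite directions (25.1%), beside 14 of 226 (6.19%) at day 7 of the same drug.

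AHCY fell by 0.82 ± 0.11 at day 1 of 5-Aza-CdR, EED by 0.74 ± 0.09, ESR1 by 0.94 ± 0.12, PGR by 0.59 ± 0.09, DNMT1, the maintenance DNA methyltransferase, by 0.48 ± 0.12, UHRF1 by 0.41 ± 0.11 and TFF1 by 0.37 ± 0.1. DNMT3B rose by 0.61 ± 0.13, with other probes from -0.09 to 0.45, and SUZ12 by 0.44 ± 0.09. Both rises became negative with scaling to a common median, at -0.18 and -0.3, and without normalization, at -0.28 and -0.4. EZH2, DNMT3A, FBXO32, GSTP1, CDKN1A and MKI67 did not pass, with changes from -0.11 to 0.38. Single samples decided the calls of UHRF1, TFF1 and DNMT1. Without Untreated A, UHRF1 was at -0.39 (adjusted p = 0.0768) and TFF1 at -0.31 (0.105), and without Untreated B, DNMT1 was at -0.33 (0.105). Without 5-Aza-CdR day 1 A, UHRF1 was at -0.36 (0.105) and TFF1 at -0.38 (0.0542), and without 5-Aza-CdR day 1 B, TFF1 was at -0.36 (0.0624) and DNMT1 at -0.42 (0.0591). Scaling to a common median gave 183 rises and 8641 falls at day 1 of 5-Aza-CdR, and no normalization 109 and 11422, beside 3767 and 4277.

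At day 7 of 5-Aza-CdR the strongest changes were rises of interferon-stimulated and germline genes. IFI27 rose by 4.47 ± 0.12 (22.2-fold, adjusted p = 4.88e-12, limma) and the germline gene VCX3B by 4.39 ± 0.1 (21-fold). From a signal at background in untreated cells, CT45A3 rose at least 16.8-fold, PAGE2B at least 14.3-fold, VCX at least 13.1-fold, PAGE2 at least 12.8-fold and MAGEA8 at least 9.56-fold, the last with another probe at 0.96. SPANXA1 rose by 3.54 ± 0.16. VCX3B, VCX, CT45A3, PAGE2, PAGE2B and SPANXA1 belong to families of near-identical copies that a probe may not tell apart. The largest falls were those of SLC39A6, which fell by 1.71 ± 0.12, CLEC2D, which fell by 1.63 ± 0.24, and NR5A2, which fell by 1.59 ± 0.09. GFRA1 fell by 1.58 ± 0.1, DTYMK by 1.54 ± 0.09, CACYBP by 1.38 ± 0.22, the receptor activity modifier RAMP3 by 1.35 ± 0.1 and the RNA export factor ALYREF by 1.33 ± 0.11. CLEC2D fell by 1.05 (adjusted p = 0.000207) without 5-Aza-CdR day 7 A. Other probes changed by 0.14 for CLEC2D, -0.09 and -1.14 for NR5A2, -0.18 for DTYMK, -0.13 and -0.11 for CACYBP, and 0 and -0.97 for ALYREF.

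Of the cancer-testis genes 25 of 54 rose at day 7 of 5-Aza-CdR, 18 of them at least 2-fold, and none fell. Adjusted over the list alone, 26 rose and 0 fell. The camera adjusted p was 1.13e-15, and 0.0134 with an estimated correlation. These 54 passed the signal filter, out of 74 with a named probe. Genes at background in all other groups, such as PAGE2, passed it only through this group. For such genes a rise was a condition of being tested, also in the other comparisons with 5-Aza-CdR day 7. Interferon genes rose in 36 of 46 cases, 18 of them at least 2-fold, with no fall (37 and 0 adjusted over the list alone; camera adjusted p = 2.74e-30, and adjusted p = 0.0134 with an estimated correlation). IFI6 rose by 3.24 ± 0.16, IFIT1 by 2.95 ± 0.09 with another probe at -0.01, and the antiviral GTPase MX1 by 2.86 ± 0.1. In the class I antigen presentation list 7 of 14 rose (9 adjusted over the list alone; camera adjusted p = 7.58e-05, and adjusted p = 0.0568 with an estimated correlation, with a median of 0.34 that became -0.07 with scaling to a common median and -0.17 without normalization), among them the peptide transporter TAP1 by 1.49 ± 0.08 and the immunoproteasome subunit PSMB8 by 0.99 ± 0.11. Inflammatory genes rose in 18 of 28 cases (22 adjusted over the list alone; camera adjusted p = 1.54e-10, and adjusted p = 0.0275 with an estimated correlation), including the chemokine CCL5 by 1.09 ± 0.1.

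Proliferation genes fell at day 7 of 5-Aza-CdR. Of the mitosis list 37 of 47 fell and none rose (41 and 0 adjusted over the list alone; camera adjusted p = 1.77e-19, and adjusted p = 0.0275 with an estimated correlation), with DLGAP5 falling by 1.24 ± 0.12 and CKS1B by 1.08 ± 0.13. Of the DNA replication list 39 of 49 fell and 1 rose (40 and 1 adjusted over the list alone; camera adjusted p = 1.74e-18, and adjusted p = 0.0134 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 1.08 ± 0.12 and the thymidylate synthase TYMS by 1.08 ± 0.13. Targets of p53 rose in 17 of 32 cases and fell in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 2.81e-07, and adjusted p = 0.0568 with an estimated correlation, with a median of 0.43 that became -0.05 with scaling to a common median and -0.16 without normalization), with TP53INP1 rising by 1.91 ± 0.1 and CDKN1A by 1.19 ± 0.15, although another probe of CDKN1A stood at -0.01. CDKN1A was not called with scaling to a common median (0.59, adjusted p = 0.241) or without normalization (0.49, 0.258). Mesenchymal and basal markers rose in 10 of 17 cases (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 3.36e-06, and adjusted p = 0.0379 with an estimated correlation, with a median of 0.46 that became -0.04 without normalization), with ANXA1 rising by 2.77 ± 0.09, TAGLN by 2.2 ± 0.12 and S100A4 by 2.08 ± 0.1. Fibroblast markers moved with them, as 4 of 10 rose (5 adjusted over the list alone; camera adjusted p = 0.00475, and adjusted p = 0.14 with an estimated correlation), among them ACTA2 by 1.22 ± 0.11 and COL3A1 by 0.56 ± 0.1. Blood cell markers rose in 5 of 15 cases (5 adjusted over the list alone; camera adjusted p = 0.0278, and adjusted p = 0.357 with an estimated correlation, with a median of 0.11 that became -0.06 without normalization), which was lost without Untreated B (adjusted p = 0.0615) or 5-Aza-CdR day 7 A (0.0534).

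Estrogen response genes fell in 22 of 38 cases and rose in 8 at day 7 of 5-Aza-CdR (23 and 9 adjusted over the list alone; camera adjusted p = 0.000671, and adjusted p = 0.206 with an estimated correlation). ESR1 fell by 1.25 ± 0.12, PGR by 0.81 ± 0.09 and TFF1 by 0.4 ± 0.1. GSTP1, a glutathione transferase often silenced by methylation in breast cancer, rose at least 2.73-fold from a signal at background, and FBXO32 rose by 1.58 ± 0.11, with other probes at 0.18 and 0.25. AHCY fell by 0.48 ± 0.11, EED by 0.5 ± 0.09, DNMT1 by 0.62 ± 0.12, UHRF1 by 0.46 ± 0.11 and MKI67 by 0.41 ± 0.1. EZH2, SUZ12, DNMT3A and DNMT3B did not pass, with changes from -0.16 to 0.18. Without Untreated A, UHRF1 was at -0.43 (adjusted p = 0.0681) and TFF1 at -0.34 (0.0919), without 5-Aza-CdR day 7 A, UHRF1 was at -0.43 (0.0772), and without 5-Aza-CdR day 7 B, TFF1 was at -0.38 (0.0725) and MKI67 at -0.37 (0.0645). The count of 5692 probes became 3460 without 5-Aza-CdR day 7 A and 3709 without Untreated B. Scaling to a common median gave 716 rises and 4999 falls, and no normalization 580 and 8736, beside 2847 and 2845.

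**Figure D2:**
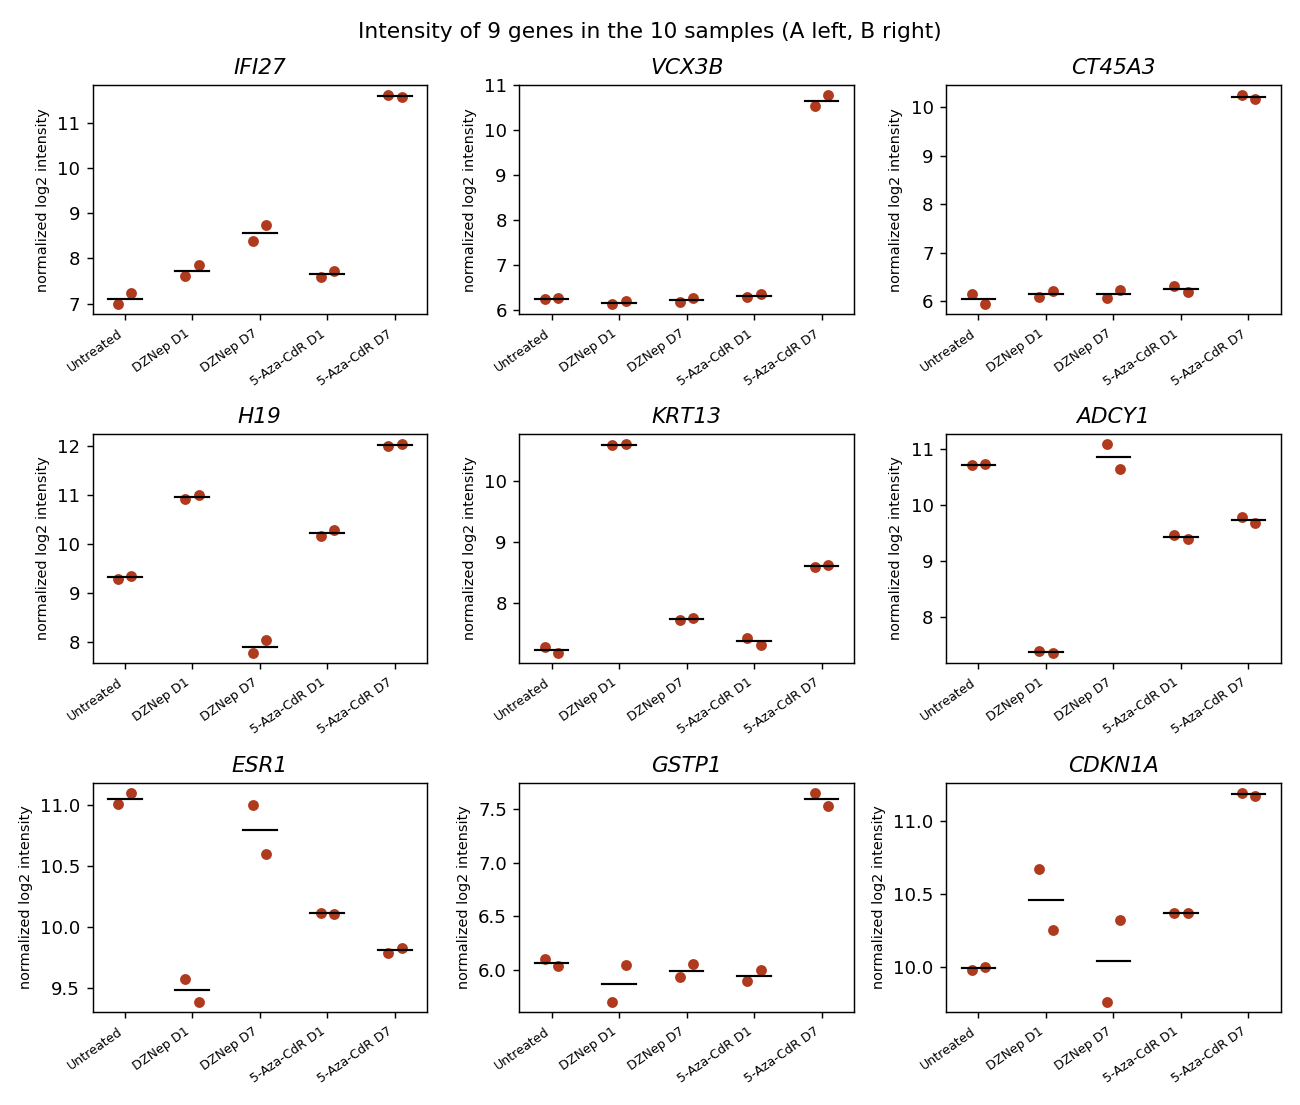
Normalized log2 intensity of 9 genes in each of the 10 samples, grouped by treatment and harvest day. Points are samples and short bars are the means of the 2 samples of a group. IFI27 averaged 7.11 in untreated cells, 8.56 in DZNep day 7 and 11.58 in 5-Aza-CdR day 7, and KRT13 was highest in DZNep day 1, at 10.6.

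**Figure D3:**
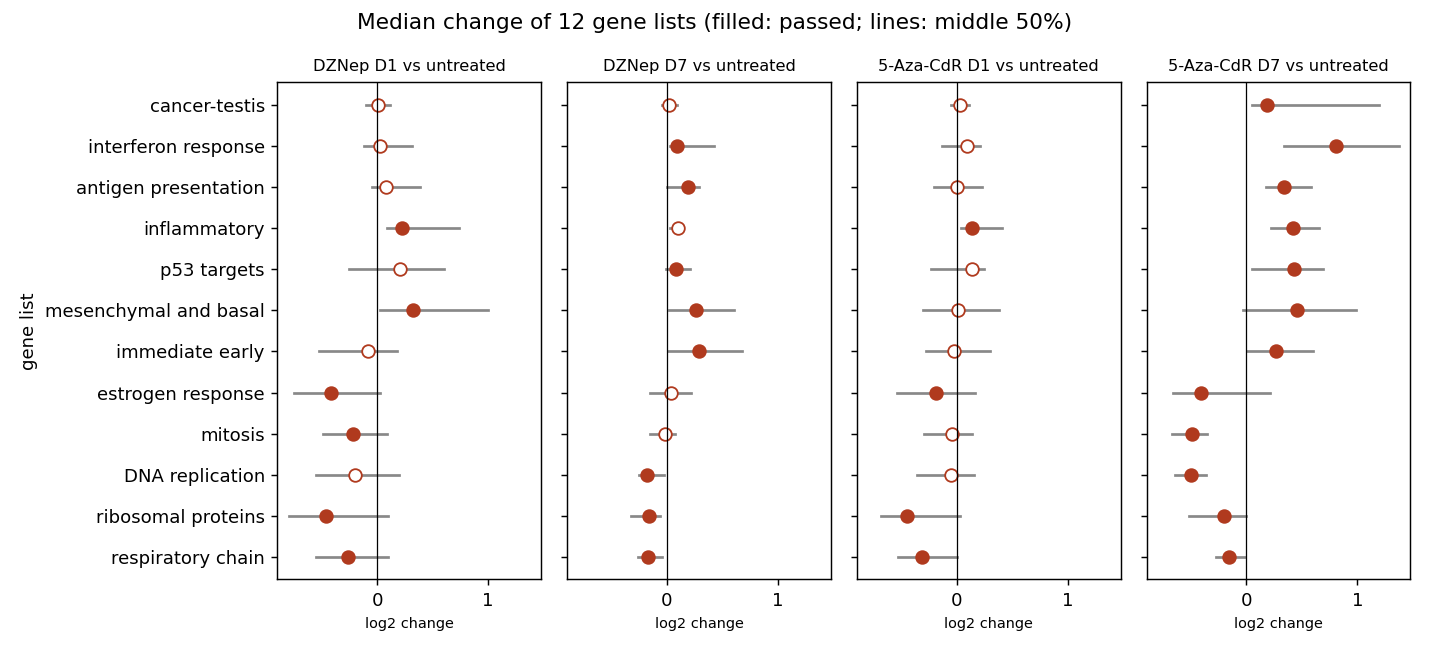
Median log2 change of the tested members of 12 gene lists in the 4 comparisons with untreated cells. Filled points passed the camera test at an adjusted p of 0.05, open points did not, and lines span the middle 50% of the members. The interferon list lies at 0.81 at day 7 of 5-Aza-CdR and at 0.09 at day 7 of DZNep, where it became -0.03 with scaling to a common median.

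The next question was whether the drugs moved the same probes. At day 1, 2489 probes rose with both drugs, 3121 fell with both and 229 moved in opposite directions, whereas independent lists of these sizes would share 654 and 857. At day 7 the shared calls were 524 rises and 226 falls with 8 opposite, against 63 and 31.1 for independent lists. Both drugs were compared with the same untreated samples, which alone makes the changes correlate. In 50 simulations of unchanged groups against shared controls the log2 changes correlated at 0.5 with a covariance of 0.00573 at day 1, while the data gave 0.73 and 0.118. At day 7 the data gave 0.61 and 0.0379, and the simulations gave 0.5 and 0.00574. With Untreated A as the control of DZNep and Untreated B as that of 5-Aza-CdR no control was shared, and the changes correlated at 0.67 at day 1 and 0.47 at day 7. With the untreated samples exchanged they correlated at 0.68 and 0.48, while the simulations gave 0 in each case. The shared calls were then 3776 and 3823 at day 1 and 207 and 211 at day 7. Dividing the untreated samples does not remove a difference common to both, such as their higher brightness, and the simulations held no such difference. The split therefore cannot tell a shared drug response from it. These correlations run across probes, which are not independent replicates. The day 7 overlap of 750 was 244 without Untreated A and 227 without Untreated B. With scaling to a common median the overlaps were 39 rises and 8051 falls at day 1 and 11 and 911 at day 7. Without normalization they were 16 and 10837 at day 1 and 31 and 5673 at day 7.

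When the drugs were compared directly at day 1, with no use of the untreated samples, 2590 probes were higher and 2874 lower with DZNep, 142 and 166 of them at least 2-fold. KRT13 was higher by 3.23 ± 0.09, NEDD9 by 2.85 ± 0.09, KRT16 by 2.67 ± 0.13, TGM2 by 2.64 ± 0.1 and ARHGDIB by 2.41 ± 0.11, with other probes between 0.62 and 1.15 for NEDD9, at 0.92 for KRT16 and at 0.5 and 0.74 for TGM2. Lower with DZNep were ADCY1 by -2.05 ± 0.12, IMPDH2 by -1.93 ± 0.11, ANKMY1 by -1.86 ± 0.11, the membrane estrogen receptor GPER1 by -1.81 ± 0.13 with another probe at -0.13, and the melanosome transport protein MLPH by -1.74 ± 0.11. Of the mesenchymal and basal markers 9 of 17 were higher with DZNep and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.00224, and adjusted p = 0.101 with an estimated correlation), with SNAI2 higher by 1.74 ± 0.1 and CAV1 by 1.48 ± 0.1. Estrogen response genes were lower in 17 of 38 cases and higher in 4 (18 and 6 adjusted over the list alone; camera adjusted p = 0.00475, and adjusted p = 0.275 with an estimated correlation), including CCND1, which encodes cyclin D1, by -1.07 ± 0.09. DNMT3A was higher, without a size because its mean lay at background with 5-Aza-CdR, whereas ESR1 was lower by -0.63 ± 0.12, SUZ12 by -0.41 ± 0.09 and MKI67 by -0.35 ± 0.1. AHCY, EZH2, EED, DNMT1, DNMT3B, UHRF1, FBXO32, PGR, TFF1, GSTP1 and CDKN1A did not pass, with differences from -0.33 to 0.33. SUZ12 did not pass without 5-Aza-CdR day 1 A (adjusted p = 0.0526) or DZNep day 1 A (0.0791), and MKI67 did not pass without 5-Aza-CdR day 1 B (0.2) or DZNep day 1 A (0.143). SUZ12 was at -0.72 (0.185) and MKI67 at -0.45 (0.184) with scaling to a common median, and without normalization at -0.77 (0.0973) and -0.49 (0.0861). Doses are not given, so the drugs cannot be set side by side at matched doses. The count of 5464 was 3605 without 5-Aza-CdR day 1 A. The split was 125 and 526 with scaling to a common median and 167 and 1320 without normalization.

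At day 7, 1370 probes were higher and 1465 lower with DZNep than with 5-Aza-CdR, 20 and 168 of them at least 2-fold. H19 was lower by -4.1 ± 0.1 (17.2-fold) and VCX3B by -4.42 ± 0.1 (21.4-fold). CT45A3 was lower by -4.06 ± 0.1 with 1 of the DZNep samples at background, PAGE2B was at least 14.3-fold lower and PAGE2 at least 12.8-fold lower. Higher with DZNep were GFRA1 by 1.44 ± 0.1, SLC39A6 by 1.34 ± 0.12, DTYMK by 1.23 ± 0.09 with another probe at 0.19, CLEC2D by 1.22 ± 0.24 (0.64 without 5-Aza-CdR day 7 A, adjusted p = 0.0152) with another probe at -0.08, and ADCY1 by 1.14 ± 0.12. Cancer-testis genes were lower in 23 of 54 cases and interferon genes in 32 of 46, with none higher (26 and 38 adjusted over the list alone; camera adjusted p = 9.68e-21 and 1.3e-35, and adjusted p = 0.0134 for each with an estimated correlation). MX1 was lower by -2.34 ± 0.1. Blood cell markers, a cell type the line does not contain, were also lower as a group (camera adjusted p = 0.0494). Among them CD14 was lower by -0.97 ± 0.1, with another probe at -0.26. That list did not pass when either untreated sample was left out. Mitosis genes were higher with DZNep in 33 of 47 cases and replication genes in 24 of 49, with none lower (43 and 32 adjusted over the list alone; camera adjusted p = 1.71e-26 and 1.86e-15, and adjusted p = 0.0204 and 0.0134 with an estimated correlation). DLGAP5 was higher by 1.01 ± 0.12. Neither CLEC2D (1.18, adjusted p = 0.315) nor DLGAP5 (0.98, 0.211) was called with scaling to a common median, nor were they without normalization (0.217 and 0.14). Estrogen response genes were higher in 18 of 38 cases and lower in 4 (21 and 5 adjusted over the list alone; camera adjusted p = 1e-06, and adjusted p = 0.121 with an estimated correlation).

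ESR1 was higher with DZNep than with 5-Aza-CdR at day 7 by 0.99 ± 0.12, PGR by 0.66 ± 0.09, UHRF1 by 0.48 ± 0.11 with another probe at 0.08, and EED by 0.47 ± 0.09. GSTP1 was at least 2.73-fold lower with DZNep, CDKN1A was lower by -1.14 ± 0.15 with another probe at 0.07, and FBXO32 by -0.85 ± 0.11 with both other probes at -0.04. EED did not pass without 5-Aza-CdR day 7 A (adjusted p = 0.0606), and UHRF1 did not pass without 5-Aza-CdR day 7 A (0.123), 5-Aza-CdR day 7 B (0.0703) or DZNep day 7 A (0.169), the last with a difference of only 0.28. The differences hardly moved with scaling to a common median, but ESR1 (adjusted p = 0.0532), PGR (0.171), UHRF1 (0.473), EED (0.593) and CDKN1A (0.245) were not called, and without normalization PGR (0.114), UHRF1 (0.299), EED (0.433) and CDKN1A (0.21) were not. AHCY, EZH2, SUZ12, DNMT1, DNMT3A, DNMT3B, TFF1 and MKI67 did not pass, with differences from -0.23 to 0.25. Leaving out 5-Aza-CdR day 7 A, 5-Aza-CdR day 7 B or DZNep day 7 A lowered the count of 2835 to 1127, 1606 and 1506. The split was 1069 and 1986 with cyclic loess, 38 and 260 with scaling to a common median and 78 and 272 without normalization.

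Between day 1 and day 7 of DZNep 5065 probes rose and 4384 fell, 493 and 600 at least 2-fold. Of the 400 pairs of bright probes of a gene with both called, 73 moved in opposite directions (18.2%). ADCY1 rose by 3.49 ± 0.12 (11.3-fold), MYO5C by 2.23 ± 0.09, CRACDL by 2.14 ± 0.09, the sulfatase SULF2 by 1.99 ± 0.12 and RMDN1 by 1.98 ± 0.12 with other probes from 0.38 to 1.88. TGM2 fell by 3.68 ± 0.1 (12.8-fold), with other probes at -1.35 and -0.81, H19 fell by 3.04 ± 0.1, ARHGDIB by 3 ± 0.11, the noncoding RNA BCYRN1 by 2.9 ± 0.32 and KRT13 by 2.87 ± 0.09. Estrogen response genes rose in 25 of 38 cases and fell in 5 (26 and 5 adjusted over the list alone; camera adjusted p = 7.57e-06, and adjusted p = 0.137 with an estimated correlation), with GREB1 rising by 1.63 ± 0.11 and its other probes at 0.25, 0.23 and 0.28. Immediate early genes rose in 14 of 27 cases and fell in 3 (15 and 4 adjusted over the list alone; camera adjusted p = 0.000564, and adjusted p = 0.205 with an estimated correlation), including EGR1 by 1.73 ± 0.1. Inflammatory genes fell in 12 of 28 cases with no rise (12 and 0 adjusted over the list alone; camera adjusted p = 0.000671, and adjusted p = 0.106 with an estimated correlation), including S100A8 by 1.34 ± 0.11.

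ESR1 rose by 1.32 ± 0.12 between the harvests of DZNep, UHRF1 by 0.76 ± 0.11 with another probe at 0.2, PGR by 0.69 ± 0.09, EED by 0.45 ± 0.09 and AHCY by 0.29 ± 0.11. DNMT3A fell at least 1.81-fold to a signal at background, DNMT3B fell by 0.78 ± 0.13 with other probes from -0.46 to -0.06, CDKN1A by 0.42 ± 0.15 with another probe at 0.02 and with overlapping samples of the harvests, and EZH2 by 0.26 ± 0.1, the last with other probes at -0.04 and 0.22. SUZ12, DNMT1, FBXO32, TFF1, GSTP1 and MKI67 did not pass, with changes from -0.17 to 0.24. EZH2 stood at 0.26 and CDKN1A at 0.1 with scaling to a common median, and at 0.33 and 0.17 without normalization. DNMT3B was at -0.24 (adjusted p = 0.678) and -0.17 (0.733) under these, and AHCY at 0.25 (0.0856) with cyclic loess. The calls of AHCY, EZH2 and CDKN1A did not hold when single samples were left out, and that of CDKN1A also not with the replicate letter as a block. Without either untreated sample their adjusted p-values were 0.0505, 0.0656 and 0.0614, without either 5-Aza-CdR day 1 sample 0.0555, 0.0504 and 0.0666, and without either 5-Aza-CdR day 7 sample 0.0572, 0.0679 and 0.0674. Without DZNep day 7 A they were 0.279, 0.267 and 0.506, with changes of only 0.18 for AHCY and -0.14 for CDKN1A. Without DZNep day 1 A that of CDKN1A was 0.417 (change -0.21), and without DZNep day 1 B those of AHCY and EZH2 were 0.311 and 0.26 (AHCY at 0.18). The split was 5423 rises and 435 falls with scaling to a common median and 7067 and 376 without normalization.

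Between day 1 and day 7 of 5-Aza-CdR 3350 probes rose and 3247 fell, 328 and 162 at least 2-fold. VCX3B rose by 4.33 ± 0.1 (20.1-fold), CT45A3 by 3.96 ± 0.1 (15.5-fold) and IFI27 by 3.94 ± 0.12 (15.3-fold), while PAGE2B rose at least 14.3-fold and PAGE2 at least 12.8-fold. SPC24, a kinetochore protein, fell by 1.79 ± 0.14, TUBB2B by 1.59 ± 0.1, NFIC by 1.53 ± 0.1 with other probes at 0.16 and -0.48, NUCKS1 by 1.48 ± 0.1 and NBPF9 by 1.44 ± 0.09 with other probes at -0.27 and 0.06. Cancer-testis genes rose in 25 of 54 cases and fell in 2, and interferon genes rose in 37 of 46 and fell in 1 (25 and 3, and 38 and 1, adjusted over the list alone; camera adjusted p = 8.91e-11 and 2.11e-24, and adjusted p = 0.0134 and 0.0201 with an estimated correlation). SAMD9 rose by 2.2 ± 0.1. Mitosis genes fell in 31 of 47 cases and rose in 1 (37 and 1 adjusted over the list alone; camera adjusted p = 1.3e-13, and adjusted p = 0.0465 with an estimated correlation), including CDC20 by 1.41 ± 0.12. Ribosome biogenesis genes fell in 22 of 36 cases and rose in 1 (25 and 3 adjusted over the list alone; camera adjusted p = 1.95e-08, and adjusted p = 0.0771 with an estimated correlation), including PA2G4 by 1.15 ± 0.12.

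GSTP1 rose at least 2.73-fold between the harvests of 5-Aza-CdR, FBXO32 by 1.41 ± 0.11 with other probes at 0.39 and 0.05, CDKN1A by 0.81 ± 0.15 with another probe at 0.04, and AHCY by 0.34 ± 0.11. MKI67 fell by 0.49 ± 0.1, DNMT3B by 0.48 ± 0.13 and EZH2 by 0.39 ± 0.1, with other probes from -0.55 to 0.05 for DNMT3B and at -0.47 and -0.16 for EZH2. EED, SUZ12, DNMT1, DNMT3A, UHRF1, ESR1, PGR and TFF1 did not pass, with changes from -0.31 to 0.23. AHCY did not pass without 5-Aza-CdR day 1 A (adjusted p = 0.12), day 1 B (0.103), day 7 A (0.089) or day 7 B (0.152). EZH2 did not pass without 5-Aza-CdR day 1 B (0.0995) or day 7 B (0.0611), and DNMT3B did not pass without day 1 B (0.146), day 7 A (0.0952) or day 7 B (0.068). Of these calls 5 ended with scaling to a common median, those of AHCY (0.51, adjusted p = 0.214), EZH2 (-0.11, 0.865), DNMT3B (-0.19, 0.828), CDKN1A (1.01, 0.117) and MKI67 (-0.23, 0.483), and without normalization the same ones did (0.196, 0.841, 0.81, 0.0993 and 0.419). The count of 6597 was 4341 without 5-Aza-CdR day 7 B. The split was 1722 rises and 134 falls with scaling to a common median and 2002 and 177 without normalization.

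The last comparison asked whether the change from day 1 to day 7 differed between the drugs, as DZNep minus 5-Aza-CdR. It differed for 4639 probes, 2371 with a positive and 2268 with a negative interaction, 306 and 473 at least 2-fold. The positive interactions were largest for ADCY1 (3.19 ± 0.17), TMEM26 (2.06 ± 0.18), TRAPPC12 (1.97 ± 0.13), the luminal secretory protein AGR3 (1.95 ± 0.21) and GFRA1 (1.8 ± 0.14). The negative ones were largest for H19 (-4.82 ± 0.14), VCX3B (-4.26 ± 0.14), KRT13 (-4.11 ± 0.12) and CT45A3 (-3.95 ± 0.14). CT45A3 lay at background in 1 sample of each DZNep group. PAGE2 was also called as negative, but it lay at background in 3 of the 4 groups, so no size is given. Interferon genes had negative interactions in 28 of 46 cases and positive in 1 (34 and 1 adjusted over the list alone; camera adjusted p = 2.66e-19, and adjusted p = 0.0245 with an estimated correlation), with IFI27 at -3.11 ± 0.18. Mitosis genes had positive interactions in 31 of 47 cases and negative in none (36 and 0 adjusted over the list alone; camera adjusted p = 2.21e-16, and adjusted p = 0.0368 with an estimated correlation), with AURKB at 1.22 ± 0.14. ESR1 (1.63 ± 0.17), PGR (0.91 ± 0.13), UHRF1 (0.81 ± 0.16) and MKI67 (0.6 ± 0.14) had positive interactions, and CDKN1A (-1.23 ± 0.22) and FBXO32 (-1.18 ± 0.16) negative ones. The interactions of DNMT3A, at background in DZNep day 7 and on average in 5-Aza-CdR day 1, and of GSTP1, at background in all groups but 5-Aza-CdR day 7, were negative and are given no size. AHCY, EZH2, EED, SUZ12, DNMT1, DNMT3B and TFF1 did not pass, with interactions from -0.3 to 0.22. Another probe of CDKN1A had an interaction of -0.01, as had another probe of UHRF1, and other probes of FBXO32 had -0.52 and 0.05. Under scaling to a common median AGR3 (2.01, adjusted p = 0.0793), UHRF1 (1.12, 0.0849), PGR (0.95, 0.0903), CDKN1A (-0.91, 0.449) and MKI67 (0.67, 0.197) were not called, and without normalization CDKN1A (-0.83, 0.383) and MKI67 (0.75, 0.0899) were not. The split was 1664 and 2423 with cyclic loess, 201 and 232 with scaling to a common median and 591 and 258 without normalization.

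**Figure D4:**
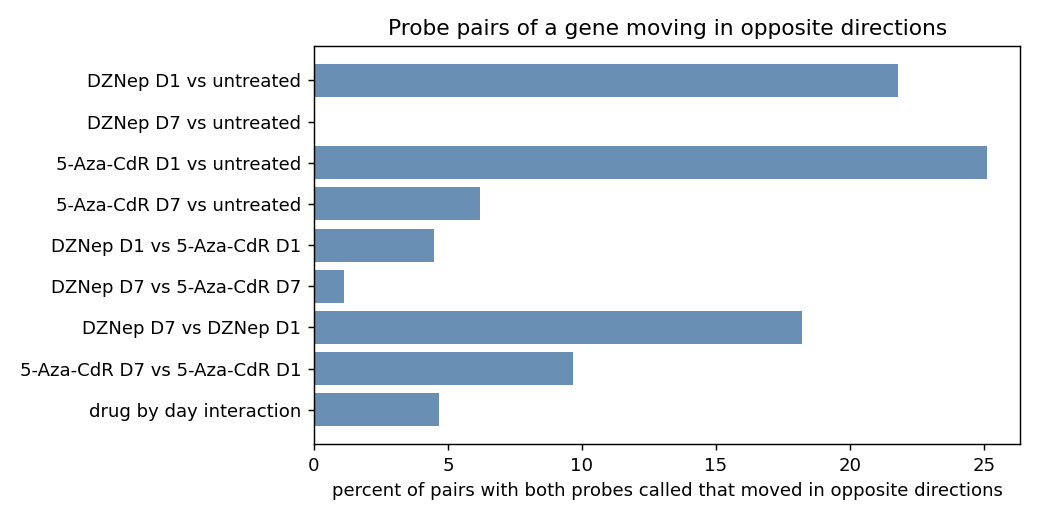
Percent of the genes with a pair of bright probes, both called, whose probes moved in opposite directions, for each of the 9 comparisons. The bars stand at 25.1% for 5-Aza-CdR day 1 and 21.8% for DZNep day 1 against untreated, and at 6.19% and 0% for the day 7 comparisons of the same drugs. The 0% for DZNep day 7 rests on only 21 pairs with both probes called, against 395 at day 1.

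Over all 33 lists and 9 comparisons, 111 of 297 list tests passed, 57 upward and 54 downward. With an estimated correlation 23 of these held, 0 of 8 at day 1 and 2 of 14 at day 7 of DZNep, and 0 of 9 at day 1 and 6 of 20 at day 7 of 5-Aza-CdR. Of the lists most often tied to Polycomb, neither HOX genes nor other developmental transcription factors passed in any comparison with untreated cells. At day 1 of DZNep 5 of 17 HOX genes rose and 1 fell (camera adjusted p = 0.186), and 18 of 71 other developmental factors rose and 9 fell (0.234). At day 7 of 5-Aza-CdR 11 of 41 genes often methylated in breast cancer rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.0603). Scaling to a common median shifted the median of all tested probes against untreated by -0.295 and -0.195 for DZNep day 1 and day 7, and by -0.222 and -0.162 for 5-Aza-CdR day 1 and day 7. Without normalization these shifts were -0.441, -0.271, -0.321 and -0.269. Single genes moved by other amounts than the median, as EZH2 did at day 1 of DZNep, from 0.33 to -0.71 with scaling to a common median. Quantile normalization gives all arrays the same distribution of intensities. The named changes are therefore relative to that common distribution, and the list tests compare each list with the other probes.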

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

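All tests of explanations in this part were chosen after the results were seen.

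The change from day 1 to day 7 differed between the drugs for 4639 probes by the interaction term. The largest positive interactions were those of ADCY1 (3.19), TMEM26 (2.06), TRAPPC12 (1.97), AGR3 (1.95) and GFRA1 (1.8). The largest negative ones among probes with a gene symbol were those of H19 (-4.82), VCX3B (-4.26), KRT13 (-4.11) and CT45A3 (-3.95). The fit gave -4.05 for PAGE2, which is neither an exact size nor a rank, since PAGE2 lay at background in 3 of the 4 groups. Among the lists 13 passed with the preset correlation and 6 of them held with an estimated one. The adjusted p of the interaction was 2.66e-19 for interferon genes, 2.21e-16 for mitosis, 8.66e-11 for cancer-testis genes, 1.41e-08 for DNA replication, 2.12e-08 for inflammatory genes and 2.35e-06 for mesenchymal markers, which are the 6 that held, at 0.0245, 0.0368, 0.0134, 0.0275, 0.0368 and 0.0379. The other 7 did not hold with an estimated correlation. These were the estrogen response (6.74e-07 preset and 0.121 estimated), p53 targets (1.61e-06 and 0.0671), histone genes (0.000598 and 0.106) and antigen presentation (0.000671 and 0.081). The rest were genes repressed by Polycomb or induced by DZNep in cancer cells (0.0175 and 0.32), lysosomal genes (0.0278 and 0.284) and blood cell markers (0.0358 and 0.359).

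The last 3 of these lists also depended on single samples or on the normalization. Genes repressed by Polycomb or induced by DZNep in cancer cells did not pass without 5-Aza-CdR day 1 B or DZNep day 1 A. Lysosomal genes did not without 5-Aza-CdR day 1 B (0.084) or 5-Aza-CdR day 7 A (0.0628), with scaling to a common median (0.294) or without normalization (0.176). Blood cell markers did not without 5-Aza-CdR day 7 A (0.08), DZNep day 1 A (0.0758) or DZNep day 7 A (0.0744). With the probes of a gene averaged, neither the list of genes repressed by Polycomb or induced by DZNep nor blood cell markers passed. At an offset of 16 blood cell markers did not pass (0.0504). Cancer-testis genes did not pass with the filter in all samples (0.324).

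The interaction takes in the wide day 1 response, in which both drugs moved many of the same probes. Unequal array brightness was tested first, on the 1183 probes that changed at least 2-fold with DZNep at day 1. Turned to their day 1 direction, these returned by a median of -0.33 between day 1 and day 7 of 5-Aza-CdR. In the 4 pairs of samples they returned by -0.34 to -0.33. The mean intensities of these samples were about equal, but their upper quartiles were 100.8 and 92.8 at day 1 and 104.9 and 111.3 at day 7. In untreated samples the upper quartiles were 130.2 and 157.7. By that measure the day 1 samples were the dimmer ones, so this test cannot decide on brightness, which stays open. A difference in RNA quality or labelling at day 1 may contribute, because the changes of a pair of probes of 1 gene correlated at 0.43 at day 1 of 5-Aza-CdR and at 0.7 at day 7. With DZNep they correlated at 0.51 and 0.56, a gap too small to decide, and the changes spread less at day 7 (SD 0.23) than at day 1 (0.59). Called pairs moved in opposite directions in 21.8% and 25.1% of cases at day 1 of DZNep and 5-Aza-CdR against untreated. Between the drugs at day 1 this was 4.49%, with a correlation of 0.69. Opposite moves were thus rarer where the day 1 groups were compared with each other. A response of the cells at day 1 stays open and was not tested separately, since RNA quality values were not used here.

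The second table of Untreated A correlated at 0.88 with the first table of DZNep day 7 A, in scanner data the comparisons do not use. Each of these samples correlated at 0.55 or 0.56 with its own other table. These correlations are between normalized log2 deviations from the mean of all arrays, over 10997 bright codes, and not between the intensities themselves. An exchange of the second tables on filing is consistent with that 0.88. The value columns lay 0.102 and 0.104 from the tables as filed, beyond the 0.0171 of the other 8 samples, and 0.0151 and 0.0119 from them with the second tables exchanged. The distance of 0.102 argues against a value table made from the tables of these 2 samples as filed, and no biological explanation was tested.

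Interferon genes rose with DZNep at day 7 as well, where 12 of 46 passed, but the list was lost with an estimated correlation (0.0568), and with scaling to a common median limma called 0 of the 46, as changes shrank and their SE grew (IFI27 from 1.45 ± 0.12 to 1.1 ± 0.28). Without normalization 3 of the 46 rose and 3 fell. RNA of 5-Aza-CdR day 7 cells in the DZNep day 7 samples might raise interferon genes, but it would bring the cancer-testis genes along in the same share. The DZNep day 7 samples reached a median of 11.4% and 15.8% of the 5-Aza-CdR rise in interferon genes and 0.183% and 0.295% in cancer-testis genes, which argues against it. Dependence on a single DZNep day 7 sample was also tested by leaving out each of them. Interferon genes still rose without DZNep day 7 A and without DZNep day 7 B, which argues against it for these samples. The untreated samples were not left out in this test, so dependence on a single untreated sample stays open. The normalization and a response of the cells to DZNep stay open.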

How the results depend on the processing

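The fits without 2 scanner tables and those with the untreated samples divided between the drugs were chosen after the data were seen, and the other alternatives before. A sample left alone in its group by leaving the other out is assumed to vary like the other groups.

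Directions were compared for the lists that passed and the named genes called above, not for other results. None of these changed direction under cyclic loess, other background corrections, filters, thresholds, variance settings or with any sample left out. The direction of a list is here that of its camera test against the other probes, not the sign of its median. With scaling to a common median 3 lists reversed in this sense. These were p53 targets in DZNep day 7 (camera adjusted p = 0.535), ribosome biogenesis in 5-Aza-CdR day 1 (0.22) and ribosomal proteins between the days of 5-Aza-CdR (0.959). The medians of other lists that passed also changed sign, as given with each list above. Without normalization p53 targets (0.706) and ribosome biogenesis (0.316) reversed. With scaling to a common median, at day 1 of DZNep EZH2 stood at -0.71, DNMT3B at -0.29, FBXO32 at -0.14 and CDKN1A at -0.63, at day 1 of 5-Aza-CdR SUZ12 at -0.3 and DNMT3B at -0.18, and between the days of DZNep EZH2 at 0.26 and CDKN1A at 0.1. Without normalization these were -0.85, -0.43, -0.29, -0.78, -0.4, -0.28, 0.33 and 0.17, and KLF2 (-0.14), CENPF (-0.12), NFKBIA (-0.02), BHLHE40 (-0.03), PPP1R15A (-0.52) and QPRT (-0.04) were negative at day 1 of DZNep, BHLHE40 (-0.15), TENT5A (-0.08) and QPRT (-0.08) at day 1 of 5-Aza-CdR and SLC4A5 (-0.14) at day 7 of 5-Aza-CdR. With scaling to a common median PPP1R15A (-0.37) at day 1 of DZNep, BHLHE40 (-0.05) at day 1 and SLC4A5 (-0.03) at day 7 of 5-Aza-CdR were also negative. EZH2 was at -0.16 at day 1 of DZNep when its probes were averaged, which follows from its disagreeing probes. The cause of the other reversals was not tested. Neither of these alternatives aligns the mean intensities, which were 466.9 and 587.1 in the untreated samples and 261.1 to 410.2 in the treated ones.

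The balance of rises and falls against untreated depended on the normalization even where the count held. With scaling to a common median 317 of 11497 calls were rises at day 1 of DZNep and 11 of 969 at day 7, and 183 of 8824 and 716 of 5715 for 5-Aza-CdR. Of the 871 calls for DZNep day 7 only 190 were then called again. Without normalization 134 of 15106 and 32 of 6663 were rises for DZNep.

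Scaling to a common median gave 651 and 298 calls between the drugs at day 1 and day 7, 5858 and 1856 between the days of DZNep and 5-Aza-CdR, and 433 in the interaction. No normalization gave 15106 and 6663 for DZNep day 1 and day 7, 9316 for 5-Aza-CdR day 7, 1487 and 350 between the drugs, 2179 between the days of 5-Aza-CdR, 849 in the interaction and overlaps of 10853 and 5704. Cyclic loess gave 1533 for DZNep day 7 and a day 7 overlap of 1293. For DZNep day 7, the drugs at day 7 and the day 7 overlap, an offset of 16 gave 251, 1764 and 226, and fits of only the groups compared gave 139, 1735 and 126. The cause was not tested for these.

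Stricter thresholds lowered counts by construction. At an adjusted p below 0.01 there were 304 for DZNep day 7, 3543 for 5-Aza-CdR day 7, 3451 and 1444 between the drugs, 4391 between the days of 5-Aza-CdR, 2691 in the interaction and 264 in the day 7 overlap. At least 2-fold were 1183, 25, 616 and 431 against untreated, 308 and 188 between the drugs, 1093 and 490 between the days, 779 in the interaction and 388 and 22 in the overlaps. Averaged probes, which are fewer, gave 6221 for DZNep day 1, 4982 for 5-Aza-CdR day 1, 6118 between the days of DZNep and a day 1 overlap of 3432. Of 111 list calls 23 were made with an estimated correlation, and fry, which asks another question, made 205.

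From the scanner tables as filed limma called 0 codes for DZNep day 7 and 0 in the day 7 overlap, averaged, blocked or as 4 repeats, with 1272, 1491 and 1970 at an unadjusted p under 0.05 for DZNep day 7. As 4 repeats the drugs differed in 4439 codes at day 7. Without the 2 tables that seem exchanged there were 870 for DZNep day 7 when averaged, 1206 with the sample as a block, and 1719 with an overlap of 1455 with no block.

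With Untreated A as the control of DZNep and B as that of 5-Aza-CdR, DZNep day 7 had 258 calls and the day 7 overlap was 207. With these exchanged they were 273 and 211, and 5-Aza-CdR day 7 had 3709. Each control is then a single sample, which lowers counts by construction.

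The replicate letter as a block raised every count of calls, for instance to 10679 and 1142 for DZNep day 1 and day 7 and to 6287 for 5-Aza-CdR day 7, and lowered list calls from 111 to 106. The 5 lists lost stood at 0.051 to 0.0534, and the call of CDKN1A between the days of DZNep was also lost. FBXO32 between the drugs at day 1 (0.0233) and SUZ12 between the days of 5-Aza-CdR (0.0413) were gained.

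Leaving out each sample in turn gave 7477 to 10590 for DZNep day 1, 258 to 1524 for DZNep day 7, 5771 to 8698 for 5-Aza-CdR day 1, 3460 to 6402 for 5-Aza-CdR day 7, 3605 to 6212 and 1127 to 3933 between the drugs, 7666 to 9136 between the days of DZNep, 4341 to 7322 between the days of 5-Aza-CdR, 3241 to 5265 in the interaction, 4027 to 6131 and 227 to 931 in the overlaps, and 102 to 120 list calls. Without Untreated B DZNep day 7 had 258, and without DZNep day 7 B it had 1524. Signal over background limits falls most, since dim probes have little room to fall.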

Other observations

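The genes in this part were chosen after their values were seen, and no explanation of them was tested.

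Some genes rose with both drugs at day 1 and were near the untreated level at day 7 of DZNep. HAUS2 changed by 1.88, -0.05, 2.08 and 0.82 in DZNep day 1, DZNep day 7, 5-Aza-CdR day 1 and 5-Aza-CdR day 7 against untreated. In that order ZNF223 changed by 1.78, 0.2, 1.91 and 0.78, TNFSF14 by 1.95, 0.01, 2.02 and 0.81 and SLC4A5 by 1.71, 0.11, 1.79 and 0.57. These genes also stood at similar intensities, and whether their probes read separate transcripts was not tested. The day 7 rises of TNFSF14 and SLC4A5 with 5-Aza-CdR did not pass without 5-Aza-CdR day 7 A, where they were 0.56 and 0.48. That of SLC4A5 did not pass without Untreated A either, where it was 0.5. Scaled to a common median, the rises at day 1 of DZNep were 0.82 for HAUS2 (0.0766), 0.72 for ZNF223 (0.126), 0.89 for TNFSF14 (0.0588) and 0.64 for SLC4A5 (0.147), and those at day 7 of 5-Aza-CdR were 0.23, 0.17, 0.21 and -0.03, none of them called. The short RNAs made by RNA polymerase III varied more between replicates, with SNAR-A1 at 1.4, -0.53, 3.06 and 3.27 (SE 0.47) and BCYRN1 at 2.23, -0.67, 1.23 and 0.27 (SE 0.32). The rise of SNAR-A1 at day 1 of DZNep did not pass without Untreated B (0.223), DZNep day 1 A (0.101) or DZNep day 1 B (0.109), and that of BCYRN1 at day 1 of 5-Aza-CdR did not without Untreated A (0.0635) or 5-Aza-CdR day 1 B (0.0578). Neither SNAR-A1 (0.32, adjusted p = 0.747) nor BCYRN1 (1.21, 0.12) was called at day 1 of DZNep with scaling to a common median, nor BCYRN1 at day 1 of 5-Aza-CdR (0.51, 0.54).

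The imprinted RNA H19 changed by 1.63, -1.41, 0.91 and 2.69 in the same order, but its day 1 rises were not called with scaling to a common median (0.56, adjusted p = 0.107, for DZNep and 0.12, 0.755, for 5-Aza-CdR) or without normalization (0.41 and 0.02). KRT13 changed by 3.37, 0.51, 0.14 and 1.38, and its rise at day 7 of DZNep did not pass without Untreated B (0.0835) or with scaling to a common median (0.15, adjusted p = 0.548), while ADCY1 changed by -3.35, 0.14, -1.3 and -0.99. A probe with no gene symbol, the most raised of all tested probes at day 1 of DZNep, changed by 4.39, 1.5, 1.03 and 2.77, of which the third was not called with scaling to a common median (0.35, adjusted p = 0.191).

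In all 4 comparisons with untreated cells 169 probes of 138 genes rose and 111 probes of 82 genes fell. Among them the interferon gene IFI6 rose by 1.45, 1.33, 1.47 and 3.24 with 1 probe, while its other probe stood at -0.34, 0.46, -0.35 and 1.72. The dehydrogenase DHRS2 rose by 2.21, 1.36, 1.22 and 2.97, the transcription factor KLF2 by 1, 1.16, 0.94 and 1.08 and BHLHE40 by 1.17, 1.1, 0.72 and 1.51. PPP1R15A rose by 0.7, 0.76, 1.08 and 1.52, TENT5A by 1.38, 0.76, 0.79 and 1.42 and QPRT by 1.15, 0.71, 0.81 and 1.52. These rises depended on the normalization, since without it KLF2 stood at -0.14, BHLHE40 at -0.03, PPP1R15A at -0.52 and QPRT at -0.04 at day 1 of DZNep. The count of 169 did not hold with scaling to a common median, where far fewer probes rose at day 7 of DZNep alone. With a common median KLF2 was called in none of the 4 comparisons (0.01, 0.69, 0.19 and 0.62), IFI6, BHLHE40, PPP1R15A, TENT5A and QPRT only at day 7 of 5-Aza-CdR, and DHRS2 there and at day 1 of DZNep. IFI6 then stood at 0.37, 0.74 and 0.71 in the first 3 comparisons. The deviations of sample A from its group mean correlated between groups at -0.05 to 0.25 over 10 pairs of groups, above 0.1 in 7 of them, across probes, which are not independent replicates.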
